A study of Mus musculus with 2 samples.

How the data were processed

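Droplet single-cell RNA sequencing had been run on cells of the mouse aorta from 2 samples, 1 per group, both from ApoE-/- mice 20 weeks old. The labels call one sample HFD and the other MSC_ITGB3, and the series text gives the purpose as a survey of aortic cell types in HFD-fed mice that had or had not received MSC_ITGB3. ApoE-/- mice lack apolipoprotein E and develop atherosclerotic plaques. Libraries were made with the Chromium 3' v3 chemistry per the labels' protocols, so each read is tied to a droplet barcode and to a unique molecular identifier (UMI), and only the 3' end of a transcript is counted.

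The authors deposited 1 matrix for the whole series, whose values are raw UMI counts per gene and barcode with no normalization. The matrix was written by Cell Ranger 6.0.1 per the file headers. The submitters' processing notes name bcl2fastq, Cell Ranger, Seurat and the mouse build mm10, and the annotation behind the counts and any version of bcl2fastq or Seurat are not given in the sources used here. The matrix holds 32285 genes, 2828620 barcodes and 102083793 nonzero entries. It is unfiltered, so it includes droplets without a cell. Barcodes end in 1 (1369431 barcodes) or 2 (1459189 barcodes), which separates 2 libraries that are called library 1 and library 2 here. No label, header or name ties either suffix to a sample. The libraries are therefore described side by side, no library is given a group, and no comparison of HFD with MSC_ITGB3 was made. Whether the depth of the libraries was equalised when they were joined is not given in the sources used here. Where a symbol is shared by more than 1 gene (78 genes), the gene identifier was kept beside it.

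Gene positions come from the GENCODE vM21 annotation of GRCm38, which is the assembly mm10, after a match of gene identifiers in which 32158 of 32285 (99.61%) were found. The list symbols Mx1 and Sepp1 are not among the matrix's gene names, and Sepp1 was measured as Selenop.

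A barcode was kept as a cell at 1000 or more UMIs, 500 or more genes and at most 20% mitochondrial UMIs. The matrix holds 110257209 UMIs in library 1 and 124266676 in library 2. The filters kept 16486 and 28497 barcodes with 86.9% and 78.4% of those UMIs, and the mitochondrial limit removed 92 and 217 barcodes. Many kept barcodes are shallow: 44.5% in library 1 and 59.6% in library 2 hold fewer than 2000 UMIs. Doublets were sought with scrublet in scanpy, which called 0 of 16486 and 0 of 28497 barcodes. Its thresholds of 0.48 and 0.67 lie above the highest scores of 0.41 and 0.45, so the caller did not work on these libraries and doublets remain in the data.

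Counts were scaled to 10000 per barcode and log-transformed, and 2000 variable genes were chosen among genes found in 10 or more barcodes. The values were scaled with a limit of 10 and reduced to 30 principal components, and a graph of 15 neighbours was clustered with the Leiden method at resolution 1.0 and seed 0, with no correction between libraries. Clusters were named from 24 sets of 5 to 11 marker genes. A marker counted as detected in a cluster at 20 CPM (a gene's share of all UMIs of a group of barcodes, on the usual CPM scale) or more and at least 2-fold above all other cells. The class with the highest mean log2 ratio of its markers was the candidate, and the name needed 3 detected markers. The modulated smooth muscle name also needed 2 smooth muscle genes at or above their level in free RNA. A cluster stayed unnamed where more markers of another class stood among its 10 leading genes by fold, or where its median UMI count was more than 3 times below that of the barcodes' own library and none of the name's markers was among those genes. Leading genes were taken at 50 CPM or more with 5 CPM added to both sides. The clustering gave 58 clusters, of which 50 were named and 8 were not. By this rule no named cluster can have more leading genes from another class's marker set than from its own, so that count does not bear on the names. Leading genes outside the sets were not counted. Class names mean resemblance in marker genes only. Macrophage-like barcodes were clustered again at resolution 0.5. A subcluster took the name of a macrophage state when 3 or more genes of that state's list were 2-fold higher there than in the other macrophage-like barcodes, the list's mean log2 ratio was above 0, and no more leading markers belonged to another class than to macrophages.

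UMIs were summed per gene, library and class and expressed as CPM of that sum. Intervals on CPM and on ratios of CPM are exact Poisson intervals and intervals on shares are exact binomial (Clopper-Pearson) intervals, all at 95%. They cover counting error only, not the spread between animals, of which nothing can be said with 1 library per sample. No p-value was computed. A count of 0 was given a limit of 3 counts, and a ratio against 0 is stated as at least the ratio to that limit. The share of barcodes with an Acta2 UMI was computed after each barcode was thinned at random to 1000 UMIs. For 17 gene lists, the median log2 ratio of library 2 over library 1 was taken over members at 10 CPM or more in either library. To both summed counts 0.5 UMIs were added before scaling, and 5 or more members had to be measured. Its percentile among 10000 random lists of the same size, matched on deciles of mean expression, describes these 2 libraries and is not a test. Counts of higher and lower members use a ratio of 1.5.

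The genes named in the text follow a fixed rule. It took, in each class with 50 or more barcodes in each library, the 5 genes with the highest and the 5 with the lowest ratio between libraries among genes at 100 CPM or more and 50 or more UMIs in the higher library. Over all kept barcodes it took 10 in each direction. It left out mitochondrial, ribosomal protein and haemoglobin genes and unnamed loci, and added examples from each gene list and Itgb3, Apoe and Xist. Some genes that the rule takes are not reported here. Genes that name a class or lead a cluster are either left out of the account of that class or named as such.

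The filters, clustering settings, marker sets, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The minimum of 10 barcodes for variable genes, the conditions on fold and leading genes for naming clusters, and the last pair of conditions for naming macrophage states were set after clusters had been seen. A minimum of 1% of barcodes for variable genes was tried after results had been seen, in the hope of fewer small clusters. It gave more of them, so the first filter was restored and the other is reported as an alternative. Added later were also a removal of the 5% of barcodes with the highest doublet scores, a depth floor applied to genes, lists and macrophage states, and the earlier naming of macrophage states by list members alone. The deep floor keeps barcodes that reach the 99th percentile of the 5000 largest barcodes of a library divided by 10, which is 5625 UMIs in library 1 and 4959 in library 2 and leaves 4130 and 3772 barcodes.

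The ratio and list steps were tested on Poisson counts simulated from the profile of both libraries together, over 26504 genes with 200 changed genes. The changed genes lay at 100 CPM or more. Free RNA, cluster naming and unequal depth of barcodes were not simulated. The test therefore does not cover changes in genes at lower levels or classes with fewer UMIs than simulated. Of genes changed 1.5-fold, 2-fold and 4-fold, 76 of 80, 76 of 80 and 38 of 40 were found within 10% of the set ratio. The intervals held the set ratio for 93.0% of 200 changed and 95.6% of 8956 unchanged genes. A list moved 1.5-fold had percentile 100, and 13 of 15 lists that were not moved lay between 2.5 and 97.5. TMM scaling by edgeR 4.0.16 in R 4.3.3 served as an alternative scaling only. Other work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, python-igraph 0.11.9 and matplotlib 3.10.9. Barcodes under 1000 UMIs entered no comparison between the libraries' classes, genes or lists, except through the alternative floor of 500 UMIs. Those with 10 to 100 UMIs served as a measure of free RNA, against which some levels in kept barcodes were set.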

Results

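Cells from the aortas of ApoE-/- mice were profiled by droplet single-cell RNA sequencing in 2 samples, 1 labelled HFD and 1 labelled MSC_ITGB3, to survey the cell types of the vessel wall with and without that treatment. The counts came as 2 libraries that nothing ties to the samples, so they are described as library 1 and library 2 and neither is given a group. Paired values below are for library 1 and then library 2. The libraries held 110257209 and 124266676 UMIs, from which 16486 and 28497 barcodes were kept as cells. Kept barcodes had median depths of 2226 and 1724 UMIs, 1229.5 and 1043 genes, and 2.6% and 3.4% mitochondrial UMIs. There are no replicates, so bracketed 95% intervals are exact and cover counting error only, and a ratio describes these 2 libraries and not the treatment.

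Apoe, the gene missing in these mice, gave few UMIs in both libraries, at 13.94 CPM (13.2 to 14.7) and 8.419 CPM (7.853 to 9.016). Its level was 31.29 and 29.78 CPM in endothelial-like barcodes, 13.55 and 7.441 CPM in macrophage-like barcodes, and 2.568 and 2.209 CPM in contractile smooth muscle-like barcodes. Low-count barcodes held 33.56 CPM (26.44 to 42.01) and 13.63 CPM (8.436 to 20.83), above the level of all kept barcodes. The endothelial-like level (28.65 to 34.11 and 25.43 to 34.65) lay within the range of low-count barcodes in library 1 and above it in library 2. Apoe (ENSMUSG00000002985) lies on chromosome 7 at 19696109 to 19699188 of GRCm38. The deleted part is not given in the labels, and a 3' tag outside it checks nothing, so these values do not test the genotype.

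Itgb3, the integrin beta 3 subunit whose symbol appears in a sample label, was higher in library 2 over all kept barcodes, at 23.45 CPM (22.49 to 24.44) and 32.76 CPM (31.64 to 33.92), a ratio of 1.397 (1.324 to 1.476). Among the classes of 50 or more barcodes per library, its level was highest in lymphatic endothelial-like barcodes of library 1 and in contractile smooth muscle-like barcodes of library 2. Contractile barcodes held 42.94 and 58.07 CPM, modulated smooth muscle-like barcodes 25.08 and 42.81 CPM (ratio 1.706, 1.461 to 1.993), and lymphatic barcodes 53.15 and 42.16 CPM. In low-count barcodes, taken as free RNA, Itgb3 stood at 19.87 CPM (14.5 to 26.59) and 36.34 CPM (27.45 to 47.19), near the level of all kept barcodes and higher in library 2 too. Part or all of the difference over all kept barcodes can therefore come from free RNA. Class shares can move it as well, since contractile barcodes held 2.022 and 2.138 times the level of other cells and took a larger share of library 2. Their level in library 2 (54.57 to 61.74) lay above that of low-count barcodes. In macrophage-like barcodes Itgb3 stood at 12.38 and 15.92 CPM, and this ratio of 1.285 turned to 0.772 after thinning and to 0.7648 in deep barcodes. Itgb3 (ENSMUSG00000020689) lies on chromosome 11 at 104608000 to 104670476 of GRCm38. Xist, the X-inactivation RNA of female cells, had 6 and 9 UMIs in all kept barcodes.

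Contractile smooth muscle-like and chondrocyte-like barcodes took a larger share of library 2. Endothelial-like, modulated smooth muscle-like and neutrophil-like barcodes took a larger share of library 1. Fibroblast-like and macrophage-like barcodes, both common, took nearly the same share of each. Chondrocyte-like barcodes made up 2.23% (2.01 to 2.46) and 10.1% (9.76 to 10.46), a ratio of 4.529. Contractile smooth muscle-like barcodes made up 7.83% (7.43 to 8.25) and 12.63% (12.24 to 13.02), and T cell-like barcodes 3.09% (2.83 to 3.36) and 4.0% (3.78 to 4.24). In the other direction, endothelial-like barcodes made up 19.99% (19.38 to 20.61) and 6.89% (6.6 to 7.19), a ratio of 2.901. Modulated smooth muscle-like barcodes, which hold smooth muscle genes together with matrix genes such as Lum and Dcn, made up 6.03% (5.67 to 6.4) and 2.29% (2.12 to 2.47). Neutrophil-like barcodes made up 4.32% (4.01 to 4.64) and 1.01% (0.89 to 1.13). The largest cluster of that class held 1.89% and 0.84% of the libraries. Others lay almost only in library 1, with 142 and 12, 99 and 0, and 52 and 1 barcodes. Fibroblast-like barcodes stood at 20.08% and 19.77%, and macrophage-like barcodes at 12.27% and 12.75%. Smaller classes were lymphatic endothelial-like (1.98% and 0.49%), dendritic cell-like (2.86% and 2.17%), Schwann-like (2.79% and 1.97%), cycling (2.47% and 2.5%), erythroid-like (1.67% and 0.76%) and pericyte-like (0.78% and 0.07%).

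**Figure D1:**
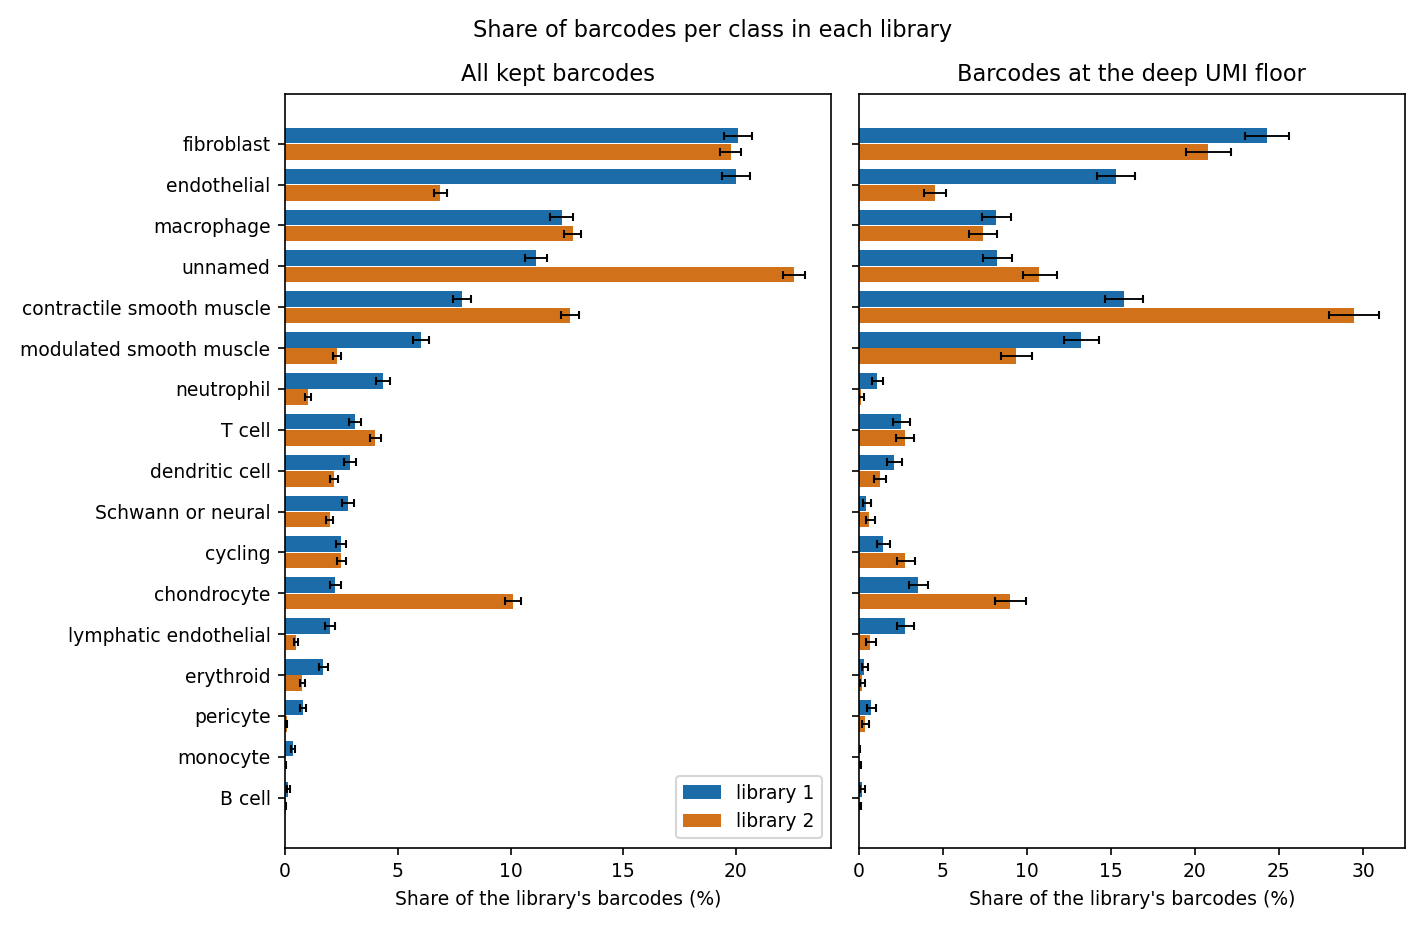
Share of each library's barcodes (percent, horizontal axis) in each class, unnamed barcodes included, over all kept barcodes on the left and over barcodes at the deep UMI floor on the right. Bars are for library 1 and library 2, with 95% exact binomial intervals that cover counting error only. Endothelial-like barcodes take 19.99% of library 1 and 6.89% of library 2 on the left and 15.28% and 4.51% on the right. Chondrocyte-like barcodes take 2.23% and 10.1% on the left and 3.51% and 8.99% on the right.

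Clusters left unnamed held 11.13% and 22.58% of the barcodes. The largest of them was a cluster led by Igfbp2, Postn, Myocd and Actg2, with 5.3% and 14.73% of the barcodes, and the next was led by Penk, Mmp13 and Prg4, with 2.3% and 5.32%. The cluster led by Igfbp2 is shallow (median 1494 UMIs) and nearest to smooth muscle, and Igfbp2 also leads the deeper modulated smooth muscle-like cluster (median 7979.5 UMIs); if its barcodes were modulated cells, that class would be larger in library 2. Another, with 10 of 10 contractile smooth muscle markers detected but led by Pln and the pericyte marker Notch3, held 1.82% and 0.64%. Depth bears on these shares, since 44.5% and 59.6% of kept barcodes lay under 2000 UMIs. Among deep barcodes the same classes gave 3.51% and 8.99% for chondrocyte-like, 15.76% and 29.45% for contractile, 15.28% and 4.51% for endothelial-like, 13.24% and 9.36% for modulated and 8.16% and 7.37% for macrophage-like. Over 9 other settings the ratio in favour of library 2 ran from 2.677 to 4.048 for chondrocyte-like and from 1.147 to 2.458 for contractile barcodes, and with 15 principal components no cluster was modulated smooth muscle-like.

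Over all kept barcodes, the 10 genes with the highest ratios in library 2 included several cartilage and bone genes. Ibsp, which encodes bone sialoprotein, stood at 8.853 and 113.4 CPM (ratio 12.81, 11.95 to 13.75). Col2a1, the main collagen of cartilage, stood at 229.6 and 1649 CPM (ratio 7.18, 7.079 to 7.282), and the cartilage genes Col11a2 (22.63 and 106.3 CPM), Acan (99.32 and 294.6 CPM), Col27a1 (46.38 and 117.2 CPM) and Sox6 (52.68 and 114.4 CPM) were also among the 10. The others were Sost, an inhibitor of bone formation that leads contractile smooth muscle-like clusters here (75.8 and 203.6 CPM), Apod (123.3 and 287.1 CPM), Crispld1 (51.16 and 119 CPM) and Susd5 (55.08 and 124.9 CPM). Genes with the highest ratios in library 1 were mostly endothelial. They include Ptprb (246.4 and 63.34 CPM), the adherens junction cadherin Cdh5 (144.2 and 38.45 CPM), von Willebrand factor Vwf (223.5 and 59.02 CPM), the vasoconstrictor Edn1 (131.3 and 34.96 CPM), Egfl7 (160 and 42.05 CPM), Mmrn2 (132.8 and 34.61 CPM) and the tight junction gene Cldn5 (172.4 and 50.19 CPM). The largest of these ratios belonged to Cd5l, a secreted macrophage protein, at 142.5 and 28.85 CPM (4.941-fold higher in library 1), followed by the neutrophil gene S100a8 at 178.3 and 44.31 CPM (4.022-fold). Cytl1, a chondrocyte marker here, went against the cartilage collagens at 900.3 and 237 CPM. On GRCm38, Ibsp (ENSMUSG00000029306) lies on chromosome 5 at 104299171 to 104311469, Col2a1 (ENSMUSG00000022483) on chromosome 15 at 97975602 to 98004695, Cd5l (ENSMUSG00000015854) on chromosome 3 at 87357881 to 87371073, and Cldn5 (ENSMUSG00000041378) on chromosome 16 at 18776847 to 18778262.

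Gene lists for smooth muscle contraction, osteochondrogenic genes and cholesterol synthesis were higher in library 2 over all kept barcodes, and lists for inflammation, leukocyte adhesion, foam cells, antigen presentation and complement were lower. The osteochondrogenic list had a median log2 ratio of library 2 over library 1 of 1.16, at percentile 100, with 6 of 8 measured members at least 1.5-fold higher, among them Tnfrsf11b (69.82 and 106.1 CPM), while Runx2 stood at 28.06 and 26.49 CPM. The contractile list had a median of 0.6 (percentile 100), with 7 of 12 members higher, such as Itga8 (274.6 and 460.8 CPM), Smtn (131.8 and 220 CPM) and Cnn1 (241.9 and 394.9 CPM). Cholesterol synthesis had a median of 0.34 (percentile 99.3) with 0 of 5 members past 1.5-fold, the highest being Insig1 (16.96 and 24.89 CPM). The inflammatory list had a median of -0.83 (percentile 0.0), with 6 of 11 members lower, including the chemokines Cxcl2 (544.4 and 265.4 CPM) and Ccl4 (193.3 and 100.3 CPM) and the cytokine Il1b (49.37 and 26.38 CPM). Leukocyte adhesion had a median of -0.62 (percentile 0.0), with 5 of 10 lower, among them the selectins Sele (35.3 and 7.783 CPM) and Selp (157.3 and 60.74 CPM). Class shares move medians taken over all kept barcodes, and within endothelial-like barcodes, whose share was 2.901 times larger in library 1, the adhesion median was -0.12 (percentile 9.6), or -0.44 (percentile 0.0) in deep ones. The foam cell list had a median of -0.5 (percentile 0.0), with 4 of 17 lower, such as Fabp5 (519.9 and 182.3 CPM), Gpnmb (226.9 and 82.62 CPM) and the scavenger receptor Cd36 (20.07 and 10.84 CPM), whereas Spp1 stood at 3788 and 4887 CPM. MHC class II genes had a median of -0.37 (percentile 0.2) with 0 of 6 past 1.5-fold, for example H2-Aa (266.1 and 197.5 CPM).

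Complement genes had a median of -0.27 (percentile 0.2) with 0 of 10 past 1.5-fold, for example C4b (269.4 and 200.8 CPM). Resident-like macrophage genes had the same median of -0.27 (percentile 0.2), with 3 of 10 lower, led by Stab1 (66.03 and 24.46 CPM), but with genes at 50 CPM or more the median was -0.07 (percentile 31.8). Other lists lay within the middle 95% of random lists. These were extracellular matrix (0.05, percentile 87.6; Col8a1 296.9 and 183.2 CPM), endothelial-to-mesenchymal genes (0.11, percentile 94.6; Snai2 13.57 and 23.42 CPM), integrins (-0.08, percentile 12.5; Itgb2 23.77 and 17.3 CPM) and mesenchymal stromal cell genes (-0.07, percentile 22.5; Eng 147.8 and 75.85 CPM). Immediate-early genes (-0.08, percentile 26.3; Hspa1b 190.3 and 303.9 CPM) and interferon response genes (0.01, percentile 40.2; Rsad2 12.02 and 5.801 CPM) belonged to the same set. So did matrix proteases (0.04, percentile 78.5), where Mmp13 (12.91 and 33.27 CPM) and Mmp3 (548.7 and 829.6 CPM) were higher in library 2 and Mmp12 (83.2 and 41.36 CPM) was higher in library 1. The median over all genes was 0.02. TMM scaling moved ratios by -0.07 over all barcodes and by -0.16 in chondrocyte-like and macrophage-like, -0.14 in dendritic cell-like and -0.12 in endothelial-like and lymphatic barcodes, and ratios are to be read relative to those shifts.

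**Figure D2:**
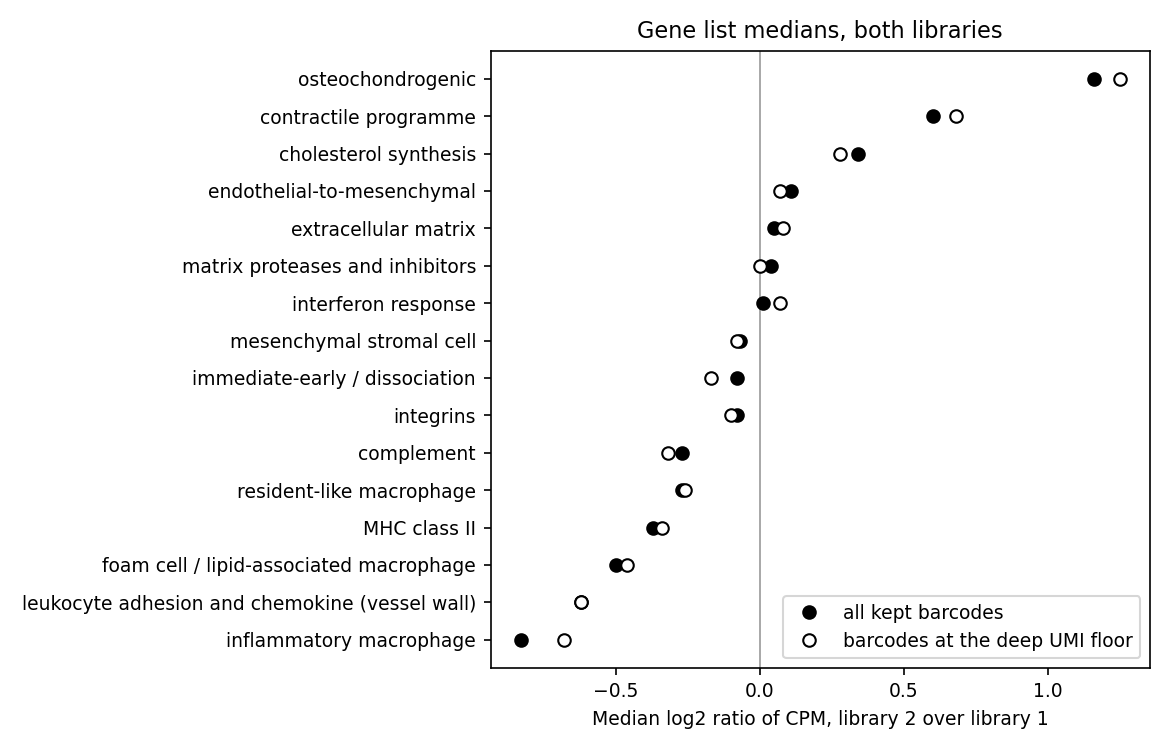
Median log2 ratio of CPM in library 2 over library 1 (horizontal axis) for each gene list, with filled points for all kept barcodes and open points for barcodes at the deep UMI floor; where a filled point is hidden, the values coincide. The osteochondrogenic list sits at 1.16 and the inflammatory list at -0.83 over all kept barcodes.

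Macrophage-like barcodes carried less of the foam cell programme in library 2. Relative to all other cells of the same library, the median log2 ratio of that list was 3.54 in library 1 and 2.49 in library 2, and of the resident-like list 5.15 and 2.45. Between libraries, 13 of 18 foam cell genes were at least 1.5-fold lower in library 2 (median -0.91, percentile 0.0). Gpnmb, a glycoprotein of lipid-loaded macrophages, stood at 1996 and 515 CPM, the fatty acid binding protein Fabp5 at 4128 and 1376 CPM and Apoc1 at 35.22 and 4.651 CPM, whereas Cd9 stood at 951 and 1138 CPM. Cd5l, which blocks macrophage apoptosis, stood at 1436 and 276 CPM (5.201-fold higher in library 1), but Cd5l, Gpnmb and Fabp5 also lead the clusters that form the class. The tartrate-resistant phosphatase Acp5 (239.8 and 73.99 CPM), the chemokine Ccl5 (140.5 and 39.89 CPM) and the acute-phase gene Saa3 (179.3 and 51.98 CPM) were higher in library 1 as well. Of 12 inflammatory genes 5 were lower in library 2 (median -0.46, percentile 0.0), with Tnf at 316.6 and 154.6 CPM, Ccl4 at 1498 and 664.4 CPM and Il1a at 46.43 and 10.64 CPM, while Egr1 stood at 627.5 and 846.9 CPM. MHC class II genes were at like levels (median -0.01), for example Cd74 at 2763 and 2809 CPM, but in deep barcodes their median was 0.39 (percentile 98.7). Of 11 resident-like genes 7 were lower in library 2 (median -0.78), among them Lyve1 at 58.49 and 10.23 CPM, but in deep barcodes that median was 0.08. Lyve1 is also among the leading genes of a cluster of the class.

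The same barcodes held more RNA typical of other cells in library 2. All 12 contractile genes were higher there (median 1.41), as were Col2a1 (8.645 and 239.7 CPM) and Apod (37.68 and 421.7 CPM), and in deep barcodes the contractile median was 1.16. The main cluster of the class also differed, with 34.9% of library 1's macrophage-like barcodes in a cluster led by Fabp5 and Cd5l and 76.52% of library 2's in another, led by Cd72 and Adgre1. In deep barcodes the foam cell median was -0.48, with 7 of 18 genes lower and 11 within 1.5-fold, and with Gpnmb at 2626 and 1070 CPM and Fabp5 at 5330 and 2627 CPM.

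Reclustering of the 2023 and 3633 macrophage-like barcodes gave 35 subclusters, of which 7 took the name of a state. Lipid-associated barcodes made up 11.3% (10.0 to 12.8) and 0.4% (0.2 to 0.6) of the class, 229 and 14 barcodes. Of these, 192 and 14 formed a subcluster led by Cd5l, Gpnmb and Atp6v0d2, and the other 37 came from library 1 alone, in a subcluster led by Bglap and Saa3 with 4 of 18 list genes 2-fold higher and a mean log2 ratio of only 0.04. Inflammatory barcodes made up 10.8% (9.5 to 12.3) and 6.4% (5.6 to 7.2), in 1 subcluster led by Cd72, Cxcl3 and MHC class II genes. Resident-like barcodes made up 8.7% (7.5 to 10.0) and 2.4% (1.9 to 2.9). Only 1 of the 4 resident-like subclusters was led by genes of its list (Lyve1, F13a1, Pf4, Ccl8), and it held 3.1% and 1.2% of the class. Another of 84 barcodes came from library 1 alone and was led by Saa3. A further 38 barcodes came from library 2 alone, in a subcluster led by Chl1 and Sfrp4 with a mean log2 ratio of only 0.1. Unnamed subclusters took 69.2% (67.1 to 71.2) and 90.9% (89.9 to 91.8), many of them led by fibroblast, smooth muscle or cartilage genes. When the 337 and 278 deep macrophage-like barcodes were clustered alone, lipid-associated barcodes made up 22.3% (17.9 to 27.1) and 7.6% (4.7 to 11.3), resident-like barcodes 10.1% (7.1 to 13.8) and 13.3% (9.5 to 17.9), and no subcluster took the inflammatory name. The deep subcluster led by Cd72 (27.3% and 35.3%, 92 and 98 barcodes) had only 2 of 12 inflammatory genes 2-fold higher and a mean log2 ratio of -0.1. Folds are taken against the other macrophage-like barcodes clustered, and these differ between the 2 runs, so the missing name need not mean a missing state. With both libraries together, Tnf stood at 471 CPM in the Cd72-led subcluster over all barcodes and at 460.2 CPM in the deep one. Ccl4 stood at 2399 and then 2977 CPM, and Cxcl2 at 3145 and then 2733 CPM. Another deep subcluster, of 82 and 26 barcodes (24.3% and 9.4%) and led by the monocyte genes Plac8, Ly6c2 and Chil3, had 5 of 12 inflammatory genes 2-fold higher. It stayed unnamed for its leading genes. A subcluster from 1 library may mark that library and not a cell state.

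**Figure D3:**
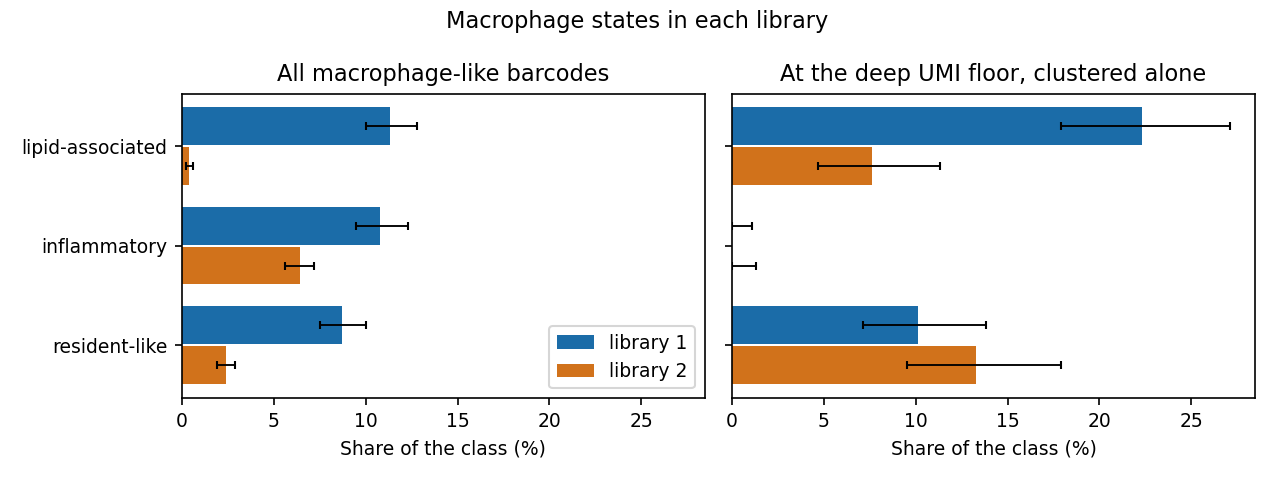
Share of macrophage-like barcodes (percent, horizontal axis) in each named state for library 1 and library 2, over all such barcodes on the left and over deep barcodes clustered alone on the right, with 95% exact binomial intervals for counting error only. Lipid-associated barcodes take 11.3% and 0.4% on the left and 22.3% and 7.6% on the right, where no subcluster took the inflammatory name.

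Contractile smooth muscle-like barcodes had like levels of the contraction machinery in both libraries but fewer transcripts of stress and inflammatory response genes in library 2. Immediate-early genes, which respond within minutes to stimuli and to tissue dissociation, had a median log2 ratio of -0.75 (percentile 0.0), with 7 of 12 lower in library 2, such as Junb (1293 and 618.5 CPM), Nr4a1 (408.6 and 210.9 CPM) and Ier2 (360.3 and 193.1 CPM). All 6 measured inflammatory genes were lower (median -0.7), including the NF-kappaB inhibitor Nfkbia (947.2 and 394.2 CPM), Cxcl1 (258.6 and 154.3 CPM) and Egr1 (1312 and 794.5 CPM). The contractile list, of which 10 of 12 genes also named the class, had a median of 0.02. Rgs5, a regulator of G protein signalling found in mural cells, was higher in library 2 at 644 and 1433 CPM (ratio 2.225, 2.164 to 2.288), as were the aldose reductase Akr1b3 (165.2 and 331 CPM) and Rsrp1 (88.86 and 152.3 CPM). Higher in library 1 were Tnnt2, a cardiac troponin (110.3 and 19.26 CPM, 5.728-fold), the glucocorticoid-responsive gene Zbtb16 (202 and 88.26 CPM) and Rgs2 (132.5 and 56.09 CPM). Apod (38.94 and 112.9 CPM) and Spp1 (114.7 and 205.9 CPM) were higher in library 2 but reversed in deep barcodes, with ratios of 0.4915 and 0.6779. Most contractile barcodes fell in different clusters, 58.79% of library 1's in a cluster of median depth 9845 UMIs and 58.42% of library 2's in one of 1492 UMIs, yet in deep barcodes the immediate-early and inflammatory medians were -0.9 and -1.18.

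Modulated smooth muscle-like barcodes, a single cluster in both libraries, showed the same direction for these lists. The inflammatory median was -0.68 (percentile 0.0), with 4 of 7 lower in library 2, led by Cxcl2 (387.2 and 185.5 CPM) and Nfkbia (975.9 and 498.1 CPM), and the immediate-early median was -0.55 (percentile 0.0), with 5 of 12 lower, such as Atf3 (512 and 270.6 CPM). Their contractile list was slightly lower in library 2 (median -0.27) and the osteochondrogenic list higher (median 0.32, percentile 100), with 3 of 7 members past 1.5-fold, including Ibsp (4.884 and 15.85 CPM) and Col2a1 (10.43 and 52.71 CPM). Both genes were more abundant and differed in the same direction in low-count barcodes of 10 to 100 UMIs (Ibsp 13.25 and 63.6 CPM, Col2a1 164.3 and 2198 CPM), so free RNA is not separated from expression by these cells. Slurp1 (40.33 and 105.3 CPM) and Rsrp1 (68.96 and 138.2 CPM) were higher in library 2. The sodium pump subunit Atp1b1 (102.3 and 41.62 CPM) and the odorant receptor locus Olfr1033 (1290 and 550 CPM) were higher in library 1. Extracellular matrix genes stood above other cells by like amounts in both libraries, with medians of 0.97 and 0.98, although 4 of those 14 genes also named the class. With deep barcodes the inflammatory, immediate-early and osteochondrogenic medians were -0.72, -0.57 and 0.34.

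Chondrocyte-like barcodes held more transcripts of cholesterol synthesis in library 2. Among single genes named for their ratio, Col10a1, the collagen of hypertrophic chondrocytes, stood at 6.134 and 120.2 CPM (ratio 19.59, 13.74 to 28.95), the imprinted zinc finger gene Plagl1 at 14.84 and 105.3 CPM, and Ibsp, which leads the class's main cluster, at 111 and 762.1 CPM. Of 8 cholesterol synthesis genes 7 were higher in library 2 (median 1.13, percentile 100), among them the squalene epoxidase Sqle (2.968 and 13.15 CPM), Idi1 (4.947 and 15.33 CPM) and Insig1 (22.76 and 57.71 CPM). Higher in library 1 were the inducible nitric oxide synthase Nos2 (207 and 25.04 CPM, 8.265-fold), the secreted chaperone Clu (2896 and 724.9 CPM), the metallothionein Mt2 (1094 and 275.5 CPM) and Chil1 (347.7 and 46.82 CPM), the last of which leads a cluster that held 117 of 367 chondrocyte-like barcodes in library 1 and 8 of 2879 in library 2. These ratios therefore compare classes of unlike cluster makeup, with the largest cluster at 67.3% and 90.59%. Inflammatory genes had a median of -0.68, with 4 of 7 lower in library 2. All 12 contractile genes (median 1.78) and 5 of 5 MHC class II genes (median 2.97) were higher in library 2, as was Ctss (10.49 and 105 CPM), a protease of macrophages. A chondrocyte-like cluster of 3 and 263 barcodes held the macrophage marker C1qa at 753.4 CPM, against 21.56 CPM in the main cluster. Whether it sets the MHC class II and Ctss values was not tested. In deep barcodes Col10a1 stood at 6.565 and 98.21 CPM and the cholesterol median was 1.4. Col10a1 (ENSMUSG00000039462) lies on chromosome 10 at 34389981 to 34397085 of GRCm38.

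Endothelial-like barcodes held fewer transcripts of some leukocyte adhesion genes in library 2, but the clusters that form the class were unequally filled, with the largest at 66.6% and 90.33% of it. Sele (91.38 and 47.79 CPM), Selp (482.7 and 281.7 CPM) and Icam1 (393 and 236.3 CPM) were the 3 of 10 members of that list past 1.5-fold downward, while 1 was higher (Ccl5, 21.1 and 41.54 CPM), and the list's median was -0.12 (percentile 9.6). In deep barcodes 4 of 9 were lower and 2 higher (median -0.44, percentile 0.0). Inflammatory genes had a median of -0.51 (percentile 0.0), with 3 of 7 lower. Among single genes, the calcium-binding protein gene Mctp1 (278.4 and 112.5 CPM), Fabp5 (312.8 and 127.5 CPM) and Zbtb16 (101.7 and 42.44 CPM) were higher in library 1, as were Tmem252 (124 and 35.3 CPM) and Gkn3 (202.9 and 88.62 CPM), which lead clusters of the class. Fabp5 is also a foam cell gene, and the class includes a cluster of 201 and 10 barcodes led by more myeloid than endothelial genes. Whether that cluster sets the Fabp5 ratio was not tested. Genes higher in library 2 were mostly of other cell types, namely Rgs5 (83.86 and 395.5 CPM), Mmp3 (139.1 and 496.2 CPM), Spp1 (535.7 and 1565 CPM), Cnn1 (65.91 and 186.5 CPM) and Ogn (105 and 294 CPM), and 11 of 12 contractile genes were higher there (median 1.19). Mmp3 is also among the leading genes of a cluster of the class. Interferon response genes had a median of 0.35 (percentile 96.0), such as Ifit1 (9.58 and 17.83 CPM) and Irf7 (7.761 and 13.73 CPM).

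Fibroblast-like barcodes held fewer transcripts of several matrix genes in library 2, and the clusters that form the class were unequally filled. The largest cluster held 38.43% and 69.31% of the class, and one led by Saa3, Cxcl14 and Lbp held 611 of 3310 and 453 of 5634 barcodes. Extracellular matrix genes had a median of -0.33 (percentile 0.0), with 4 of 14 lower, among them the fibronectin gene Fn1 (2552 and 1594 CPM) and Postn (351.5 and 208.8 CPM), while the elastin gene Eln stood at 572.5 and 760.3 CPM; 5 of the 14 genes also named the class. Haptoglobin (Hp, 497.8 and 193.3 CPM), C1qtnf6 (110 and 39.93 CPM) and Zbtb16 (116.7 and 42.91 CPM) were higher in library 1, as was Saa3 (1326 and 518.3 CPM), which leads a cluster of the class. Complement genes stood above other cells by like amounts, with medians of 1.88 and 1.84. All 12 contractile genes were higher in library 2 (median 1.19, and 0.75 in deep barcodes), with Myh11 at 116.5 and 346.1 CPM.

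Among genes higher in library 1, T cell-like barcodes had the largest ratio for Gzma, the gene of the cytotoxic protease granzyme A, which stood at 594.4 and 33.75 CPM (17.61-fold higher in library 1) and at 586.6 and 64.29 CPM in deep barcodes, and which leads the smaller of the class's 2 clusters. That cluster held 201 of 509 and 150 of 1141 T cell-like barcodes, so the ratio and the list below compare classes of unlike makeup. Of 11 measured T helper and regulatory genes 4 were lower in library 2 and 3 were higher (median -0.34, percentile 0.9), with the cytotoxic protease gene Gzmb (205 and 48.31 CPM) and the transcription factor gene Tbx21 (79.26 and 39.71 CPM) among the first and the interleukin gene Il17a (28.43 and 72.14 CPM) and the receptor gene Il2ra (34.03 and 69.16 CPM) among the second. That median turned to 0.31 in deep barcodes. Relative to other cells the list stood at medians of 6.7 and 5.99. Genes of other cell types were again at unlike levels, with Ibsp at 0 and 173.4 CPM (at least 134.2-fold higher in library 2), all 12 contractile genes higher in library 2 (median 1.54), and the endothelial genes Ptprb (143.9 and 15.22 CPM) and Vwf (143 and 20.85 CPM) higher in library 1.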

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

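Each test in this part was chosen after the result it bears on had been seen. No biological explanation was tested, because neither library can be tied to a sample and the design therefore gives no group to set against them.

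Barcodes with 10 to 100 UMIs, which were not kept as cells and serve in the report only as a background, carried cartilage and bone RNA. They are listed because the counts lie above the limit that a count of 0 allows, which shows detection and not the source of the RNA. Library 1 had 65270 such barcodes with 2264389 UMIs, and library 2 had 39379 with 1540880. Col2a1 stood at 164.3 CPM in library 1 (372 UMIs) and 2198 CPM in library 2 (3387 UMIs), against limits of 1.325 and 1.947 CPM. Ibsp stood at 13.25 CPM (30 UMIs) and 63.6 CPM (98 UMIs) against the same limits. Acta2, the smooth muscle actin, stood at 4886 and 7234 CPM in these barcodes.

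If this cartilage RNA was free in the suspension, it could have made barcodes of other cells look chondrocyte-like and so set the shares of 2.23% and 10.1%. Deep barcodes hold more RNA of their own, so under that explanation the shares there should differ by less than 1.5 times. They were 3.51% and 8.99%, a ratio of 2.56, which argues against free cartilage RNA as the whole source of the difference. It may still add to it among shallow barcodes, since the ratio over all kept barcodes was 4.529. A difference in how much cartilage was taken with each aorta stays open and was not tested.

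The share of endothelial-like barcodes was 19.99% in library 1 and 6.89% in library 2. If the floor of 1000 UMIs had removed endothelial cells from library 2 alone, a lower floor should bring the shares within 1.5 times of each other. At 500 UMIs and 300 genes they were 20.06% and 7.06%, a ratio of 2.84, which was the lowest under 3 other floors. The stricter floors among these cannot restore lost barcodes and do not bear on this. Had a larger share of another class lowered all others alike, endothelial-like barcodes per macrophage-like barcode would be near equal, but they were 1.63 and 0.54, a ratio of 3.01. Both values argue against their explanations as the whole source, and a different yield of endothelial cells at dissociation or a difference between the aortas may remain.

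Macrophage-like barcodes under 2000 UMIs held smooth muscle and fibroblast RNA. A single source of free RNA with the makeup of the low-count barcodes would raise the markers of each cell type by a like fraction of their low-count level. Each fraction is the CPM in macrophage-like barcodes under 2000 UMIs minus that in deep ones, divided by the low-count CPM. It is negative where deep ones hold more. The median fractions were 44.67% (range over genes 39.14 to 77.1) for smooth muscle, 115.2% (53.6 to 151.6) for fibroblast and 54.43% (-66.48 to 81.38) for endothelial markers in library 1, and 45.45% (34.83 to 74.15), 86.46% (33.78 to 126.1) and 19.91% (-37.3 to 28.99) in library 2. The spread of the medians, 2.58-fold and 4.34-fold, argues against that source alone. The ranges overlap, though, in library 1 and between smooth muscle and fibroblast in library 2. The lowest median in library 2 is that of the endothelial set. That set holds Fabp4, also a foam cell gene, so the macrophages' own RNA can lower its values where Fabp4 is counted. Doublets with smooth muscle cells and a free RNA of another makeup cannot be told apart here: 66.0% (63.0 to 68.9) of 1047 such barcodes in library 1 and 88.0% (86.6 to 89.3) of 2314 in library 2 held an Acta2 UMI at 1000 UMIs, where an even spread would give 94.1% and 99.5%, and the doublet caller did not work.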

How the results depend on the processing

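The alternatives named here as chosen after seeing the data are the removal of high doublet scores, the 1% minimum for variable genes, the state names by list members alone, and the deep floor for genes, lists and macrophage states; the others were planned. No paired analysis was possible because each group has 1 library, the columns carry no replicate numbers and no test was run. The cause was not tested for any value below. Keeping called doublets changed nothing because none had been called, so it says nothing about doublets. Depth limits most of these results: a class found among shallow barcodes takes its share from the floor and from the clustering, and 16 of 58 clusters came to over 95% from 1 library. In each of 9 other settings with a usable value, endothelial-like barcodes had the larger share in library 1 (2.649 to 3.852 times) and chondrocyte-like (2.677 to 4.048 times, all below the 4.529 of the report), contractile (1.147 to 2.458 times) and T cell-like barcodes (1.072 to 1.347 times) in library 2. Modulated smooth muscle-like barcodes had the larger share in library 1 in the 8 settings that held the class (1.388 to 2.903 times). The order of fibroblast-like and macrophage-like shares turned in some settings.

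Class shares are in percent, library 1 then library 2; a share named for 1 library moved there only. With 15 principal components they were chondrocyte-like 4.0 and 14.73, contractile 8.56 and 13.12, endothelial-like 13.1 and 3.51, fibroblast-like 17.76 and 15.53, macrophage-like 14.12 and 16.18, and modulated 0.0 and 0.0. With floors of 2000 UMIs and 1000 genes, 9083 and 11488 barcodes were kept, with chondrocyte-like 2.7 and 10.93, endothelial-like 18.51 and 6.39, fibroblast-like 17.55 and 12.29, macrophage-like 9.42 and 11.49, and modulated 9.09 and 4.4. With 500 UMIs and 300 genes, library 2 kept 49220 barcodes, and shares were chondrocyte-like 6.67 and 18.44, contractile 3.57 and 4.95, macrophage-like 14.35 and 15.08, and modulated 3.54 and 1.77. With the deep floor, 4130 and 3772 barcodes gave chondrocyte-like 5.04 and 13.49, contractile 17.68 and 30.09, endothelial-like 17.68 and 4.59, fibroblast-like 24.48 and 20.36, macrophage-like 7.07 and 6.57, and modulated 14.75 and 10.63. With at most 10% mitochondrial UMIs they were chondrocyte-like 5.18 and 18.8, contractile 11.38 and 24.05, endothelial-like 18.73 in library 1, fibroblast-like 19.22 in library 2, macrophage-like 13.09 and 12.22, and modulated 6.76 and 3.08.

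At resolution 0.5 shares were chondrocyte-like 2.88 and 8.1, contractile 4.56 and 5.23, endothelial-like 22.06 in library 1, fibroblast-like 21.32 and 21.48, macrophage-like 11.09 in library 1, and modulated 6.63 and 2.57. At resolution 2.0 they were chondrocyte-like 3.21 and 12.1, contractile 7.35 in library 1, endothelial-like 18.83 and 6.5, fibroblast-like 17.49 and 18.03, macrophage-like 10.29 in library 1, and modulated 5.02 and 3.0. Without the 5% of barcodes with the highest doublet scores they were chondrocyte-like 4.57 and 16.38, contractile 9.85 and 18.27, endothelial-like 19.37 in library 1, fibroblast-like 18.68 and 15.81, macrophage-like 10.89 and 11.7, and modulated 5.66 and 1.95. With variable genes found in 1% of barcodes they were chondrocyte-like 5.06 and 17.77, contractile 6.37 and 15.66, endothelial-like 6.45 in library 2, fibroblast-like 24.41 and 28.09, macrophage-like 9.76 in library 1, and modulated 3.56 and 1.68.

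Shares of macrophage states moved with the clustering. At resolution 0.3 within the class, inflammatory stood at 0.0 and 0.0 and lipid-associated at 20.9 and 7.0. At resolution 1.0 lipid-associated stood at 9.3 in library 1. Named by list members alone, inflammatory stood at 19.9 and 7.3 and lipid-associated at 13.8 and 1.4. With variable genes found in 1% of barcodes, inflammatory stood at 5.9 and 4.2 and lipid-associated at 15.2 and 2.1. A 0 here means that no subcluster took the name. With the deep floor, inflammatory stood at 0.0 and 0.0, lipid-associated at 22.3 and 7.6 and resident-like at 10.1 and 13.3. Lipid-associated barcodes took the larger share in library 1 in each of these settings.

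In deep barcodes the immediate-early list over all kept barcodes left the middle of random lists, with a median of -0.17 (percentile 1.2). Ratios of library 2 over library 1 that reversed there were Apod 0.4915 and Spp1 0.6779 in contractile, Apod 0.1785 and Gpc3 0.9073 in neutrophil-like (each on 1 UMI in library 2), and Itgb3 0.7648 in macrophage-like barcodes. List medians that reversed there were T helper 0.31 in T cell-like, cholesterol synthesis -0.26 and resident-like genes -0.53 in neutrophil-like, complement -0.52 and resident-like genes -0.22 in chondrocyte-like, contractile -0.37 in cycling, endothelial-to-mesenchymal -0.14 and matrix proteases -0.24 in dendritic cell-like, and interferon response 2.61 in erythroid-like barcodes. Without mitochondrial, ribosomal protein and haemoglobin genes, the complement median in contractile barcodes was 0.21. With genes at 50 CPM or more, the resident-like list over all kept barcodes had a median of -0.07 (percentile 31.8). Thinning to 1000 UMIs turned Itgb3 in macrophage-like barcodes to 0.772.

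Of 192 gene ratios, 152 stayed within their counting interval with the floor of 2000 UMIs, 188 without mitochondrial, ribosomal protein and haemoglobin genes and 140 with TMM scaling, and the rest moved without a change of direction. Thinning kept 77 of 190 and the deep floor 85 of 187 within the interval. Of 202 list medians within classes, 196 kept their side of the middle 95% without those genes, 132 of 200 did so with the deep floor and 139 of 156 at 50 CPM.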

Other observations

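The deep-barcode values in this part come from an alternative chosen after the data had been seen, and nothing in it was tested.

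Smaller classes differed in recognisable gene groups. Interferon response genes were higher in library 2 in Schwann-like barcodes, where 9 of 10 measured members passed 1.5-fold (median log2 ratio 1.71, percentile 100), with Ifit1 at 13.5 CPM in library 1 and 238.2 CPM in library 2 and Ifit3 at 23.03 and 284.2 CPM. Rbfox1, a neuronal splicing factor, stood at 3.177 and 253.8 CPM there, while Cxcl2 (541.6 and 105.2 CPM) was higher in library 1. Neutrophil-like barcodes of library 1 held more Cxcl10, an interferon-induced chemokine (339.3 and 32.7 CPM), which also leads a cluster of 142 and 12 barcodes. Several other interferon genes went the other way in the neutrophil-like class, with Ifit3 at 31.33 and 163.5 CPM and 6 of 11 list members higher and 3 lower in library 2 (median 0.83). The largest neutrophil-like cluster held 43.68% and 83.62% of the class, so these values also compare unlike makeups. The Apod (138.8 and 2983 CPM) and Gpc3 (39.52 and 161.7 CPM) ratios of this class reversed in deep barcodes, but there library 2 had 5 barcodes with 1 UMI of either gene (22.01 CPM, 0.5573 to 122.6), so the reversal says little.

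Lymphatic endothelial-like barcodes, 326 and 139 in number, had 9 of 10 leukocyte adhesion genes lower in library 2 (median -1.21, percentile 0.0), among them the chemokine Ccl2 (269.8 and 56.22 CPM), and Cxcl2 stood at 519.1 and 60.44 CPM. In deep lymphatic barcodes 6 of 9 were lower (median -0.74). Genes of other cell types differed in the same deep barcodes, with 10 of 10 contractile genes (median 1.62) and 5 of 5 MHC class II genes (median 2.02) higher in library 2. Saa3 stood at 205.3 CPM in library 1 with 1 UMI in library 2 (1.405 CPM). Dendritic cell-like barcodes held more Mmp12 in library 1 (108.9 and 34.88 CPM), together with the neutrophil gene S100a8 (103.2 and 6.228 CPM), and more Spp1 in library 2 (288.5 and 1486 CPM). The cartilage genes Col2a1, Comp and Acan and the smooth muscle gene Myocd were also among the highest library 2 ratios of this class. Free RNA is therefore not separated from expression of Spp1 by these cells. Some genes recurred across the 13 classes with 50 or more barcodes in each library. Col2a1 was among the highest ratios in library 2 in 7 of them, Apod in 5 and Spp1 in 4, and Bmp6 and Saa3 were among the highest in library 1 in 4 each. Low-count barcodes held Col2a1 at 164.3 and 2198 CPM, so its recurrence need not mean expression by those classes.

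Some named clusters were led by genes outside their class. A fibroblast-like cluster of 611 and 453 barcodes was led by the acute-phase and chemokine genes Saa3, Cxcl14, Lbp, Il33 and Ccl7. An endothelial-like cluster of 201 and 10 barcodes had more myeloid genes (Clec4n, Cd72, C5ar1, Ms4a7 and Cd14) than endothelial genes among its 10 leading ones, with C1qa at 1082 CPM, and it counts in the endothelial-like share with 1.22% and 0.04% of the libraries. Another of 90 and 43 was led by Ackr1, the marker of venules, with the cartilage gene Acan and with Nos2. An erythroid-like cluster of 0 and 69 barcodes was led by 4 haemoglobin genes and at least as many cartilage genes, such as Col11a1, Col9a1 and Col2a1, and it makes up 69 of the 218 erythroid-like barcodes of library 2. Within lipid-associated macrophage-like barcodes, the cholesterol exporter Abca1 stood at 708.6 and 813.0 CPM, and Gpnmb at 6070 and 5960 CPM, although only 14 barcodes of library 2 had that state in the main clustering. When deep barcodes were clustered alone, 21 of 278 in library 2 had it. Both genes are in the list that names the state and Gpnmb leads its main subcluster, so like levels are partly set by the naming.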
